A study of Mus musculus with 8 samples.

How the data were processed

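Expression was measured in whole skin of newborn FVB mice on Affymetrix arrays. Per the labels' protocols, total RNA was extracted from 30 mg of skin and labelled with biotin, and per the series text each array held a pool of RNA from 3 animals of a genotype, with 2 arrays for each of 4 genotypes. RMA, which corrects background, normalizes arrays by quantiles and summarizes probes, was used per the submitters' processing notes, which give no version. The deposited value is a standardized score: each of the 22690 probe sets had mean 0 and SD 1 over the 8 arrays, with no missing value. No label records this standardization, and whether it was applied to log or linear values is not given in the sources used here. A z-score over 8 values cannot exceed 2.47 in size, so the size of a difference saturates and says how cleanly the arrays part, not how large the change in RNA was. Signal over background cannot be read from the scores either.

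Groups and replicate numbers came from the sample titles. The sample titles number the 2 arrays of a genotype but do not say whether they are separate pools. P-values of the linear model therefore measure the spread between the duplicate arrays, which need not be the spread between animals. Probe sets were named through the platform annotation and a mouse gene table: 20380 of the 22626 tested probe sets had 1 gene symbol, 691 had several and 1555 had none, and no gene was named from a probe set with several. Of the single-gene probe sets, 20351 had a gene identifier in the gene table and 0 symbols changed. For gene lists and named genes, 1 probe set stood for each of 12393 genes, of which 4956 had 2 or more. It was chosen without its values, by preferring probe set names that end in _at, then _a_at, _s_at and _x_at, and then the lowest number, because the rule fixed earlier, the highest mean, cannot be applied to scores of mean 0. Other probe sets of a called gene had an opposite sign for 9 of 18 such genes in p107 loss in pRb+/+ skin, 18 of 70 in p107 loss in pRb-/- skin, 1 of 14 in pRb loss in p107-/- skin and 43 of 133 for loss of both proteins.

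A linear model with a coefficient per genotype was fitted to the scores with limma 3.58.1 in R 4.3.3, over all 8 arrays, leaving 4 residual degrees of freedom. The design fixed before the data were examined named log2 values and limma's moderated test. On standardized scores, moderation pools variances that the standardization has already tied to each probe set's differences, whereas the unmoderated test of the model gives the same result on scores as on the values they were made from. The unmoderated test was therefore used as the main test. It was chosen once the values were found to be scores, from a first simulation run before any call on the arrays was computed, but after array correlations and the values of a few genes had been looked at. The planned moderated test called 0 probe sets in every comparison, so all counts of changed probe sets rest on this change. The tests on simulated data given here were run afterwards. For loss of both genes over 22626 probe sets, with 200 changed, the unmoderated test recovered 6%, 26%, 80% and 100% at shifts of 4, 8, 16 and 32 noise SD, with 2.8% false calls and 5.1% of unchanged probe sets at an unadjusted p below 0.05, while the moderated test called 0. With 4000 changed, it recovered 35.8%, 94.7%, 100% and 100%, with 4.2% false calls. There the moderated test called 3735 probe sets against 3451, and put 7.7% of unchanged probe sets below an unadjusted 0.05. Moderation can therefore call on scores, but its error rate moved with the share of changed probe sets. P-values were adjusted by Benjamini-Hochberg over the 22626 probe sets, with a threshold of 0.05. The contrasts were pRb loss where p107 was kept, p107 loss in pRb+/+ skin, p107 loss in pRb-/- skin, pRb loss in p107-/- skin, loss of both and the interaction, and an F test compared all 4 genotypes.

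Before the data were examined 29 gene lists were fixed: Rb family and E2F factors, S phase and DNA replication, G2 phase and mitosis, CDK inhibitors and G1 cyclins, p53 targets, apoptosis, basal keratinocyte, spinous layer, granular layer and cornified envelope, hyperproliferation and stress keratinocyte genes, hair follicle, Wnt, Hedgehog and Notch response, AP-1 and immediate early genes, interferon response, inflammatory cytokines and chemokines, lipid and sterol synthesis, sex-linked genes, and markers of fibroblasts, adipocytes, skeletal muscle, endothelium, macrophages, mast cells, lymphocytes, erythroid cells, melanocytes, Schwann cells, smooth muscle and sebocytes. They were tested with limma's camera on the normal scores of the unmoderated model statistics, with a preset correlation of 0.01, and adjusted over the 29 lists within a comparison. Camera on the planned moderated statistics was not run. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. With the preset correlation its p-value takes the genes of a list as nearly independent units. It does not measure the spread between arrays or animals. With a correlation estimated from the residuals, 43 of 50 calls held. In simulated data a list of 40 genes shifted by 1.5 noise SD was called higher, and 4% of 200 unshifted lists fell below an unadjusted 0.05. Noise there was drawn independently for each gene, so this rate does not cover lists of correlated genes. In the arrays the estimated correlation ran from -0.156 for sex-linked genes to 0.212 for basal keratinocyte genes.

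Named genes followed a rule fixed in advance: Rb1 and Rbl1 first, then per comparison the 10 largest differences in each direction among genes past the threshold whose arrays did not overlap (5 for pRb loss in p107-/- skin, loss of both and the interaction, the last without the condition on overlap), or the 3 largest in each direction as values where none passed, and from each list up to 4 members with the smallest adjusted p, or 2 with the largest difference as values. Members of the Rb family, E2F and sex-linked lists could be named in any comparison. The rule named log2 fold changes, in place of which the difference in SD units was used. For reasons of space some genes taken by the rule are not described. Control probe sets were compared by exact permutation tests, chosen after the arrays were examined. Differences between list medians per array were fitted with the same linear model, also chosen afterwards. The alternatives were quantile normalization, subtraction of array medians, the moderated test, a replicate block, array weights, fits of only the genotypes compared, gene averages and each array left out. For lists, an estimated correlation and limma's fry were also used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.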

Results

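Whole skin of newborn FVB mice was profiled on Affymetrix expression arrays in 4 genotypes that differ in the retinoblastoma protein pRb, encoded by Rb1, and its relative p107, encoded by Rbl1. Both proteins bind E2F transcription factors and restrain entry into S phase. The groups were pRb+/+, pRb-/-;p107+/+, pRb+/+;p107-/- and pRb-/-;p107-/-, with 2 arrays each and a pool of RNA from 3 animals on each array. The labels of the pRb+/+ arrays do not state their p107 genotype, which is taken here as wild-type. Loss of pRb or p107 below names the genotype of the label. Neither protein was measured, and whether dermal cells of pRb-/- skin lack pRb is not known here. The deposited values were z-scores: every probe set had mean 0 and SD 1 over the 8 arrays. A difference of 1 therefore means 1 SD of that probe set over all arrays, and neither expression levels nor fold changes can be read from the values. Differences below are in these SD units with the standard error of the linear model, and the number of arrays limits their precision. Of 22690 probe sets, 64 were array controls and 22626 were tested, and the named genes rest on 1 probe set per gene for 12393 genes.

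The targeted genes were measured first. Rb1, measured by 1 probe set, had a mean z-score of 1.14 ± 0.1 (SD, n = 2 arrays) in pRb+/+ skin, 0.07 ± 0.41 in pRb-/-;p107+/+ skin, 0.21 ± 0.26 in pRb+/+;p107-/- skin and -1.42 ± 0.2 in pRb-/-;p107-/- skin. It fell in pRb-/-;p107-/- skin against pRb+/+ skin, by 2.56 ± 0.27 (SE, limma linear model, adjusted p = 0.0391). The difference for pRb loss was -1.07 ± 0.27 where p107 was kept (adjusted p = 0.266) and -1.63 ± 0.27 in p107-/- skin (adjusted p = 0.17), and neither passed the threshold. Rb1 was also lower in pRb+/+;p107-/- than in pRb+/+ skin, by a difference of -0.93 ± 0.27 that did not pass (adjusted p = 0.198). The first of the Rbl1 probe sets, which stands for the gene here, averaged 0.14 ± 0.09 in pRb+/+, 1.22 ± 0.11 in pRb-/-;p107+/+, -1.37 ± 0.21 in pRb+/+;p107-/- and 0 ± 0.44 in pRb-/-;p107-/- skin. Its difference for p107 loss was -1.51 ± 0.25 in pRb+/+ skin (adjusted p = 0.103) and -1.22 ± 0.25 in pRb-/- skin (adjusted p = 0.126). The second Rbl1 probe set had the same signs for p107 loss, with differences of -2.13 ± 0.55 (adjusted p = 0.175) and -0.85 ± 0.55 (adjusted p = 0.478). Against pRb+/+ skin, the pRb-/-;p107-/- arrays differed by -0.14 ± 0.25 in the first Rbl1 probe set (adjusted p = 0.789) and by -0.97 ± 0.55 in the second (adjusted p = 0.391). Lower Rbl1 was thus not found there by these probe sets. Where these probes lie relative to the deleted parts of the genes is not given in the sources used here. Which cells of the skin carry the deletions was not measured either, so these probe sets are a limited check of the labels.

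**Figure D1:**
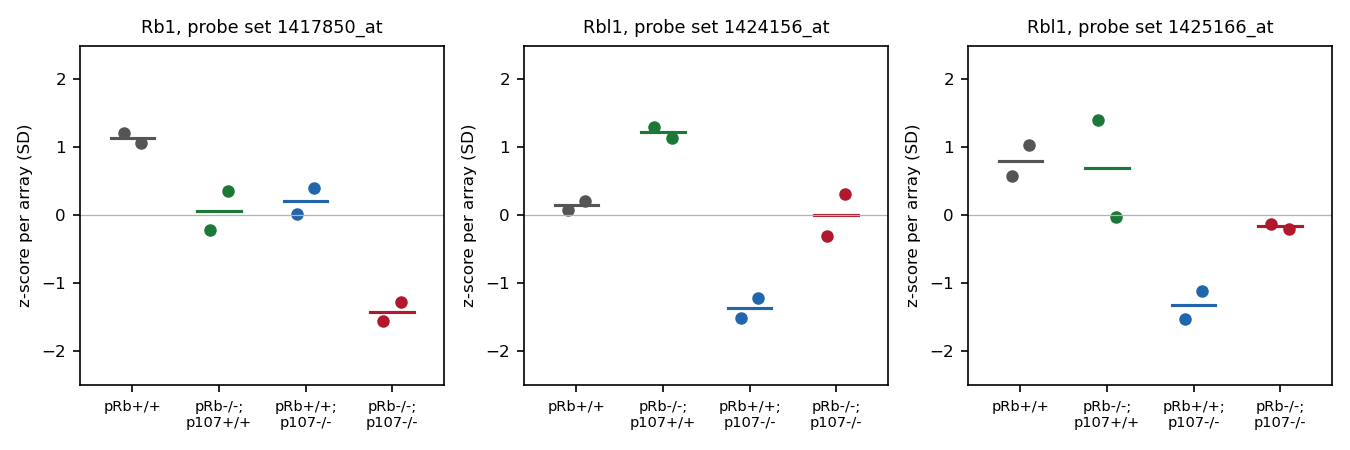
Z-score of Rb1 and of both Rbl1 probe sets on each array (vertical axis, in SD of the probe set over the 8 arrays) by genotype (horizontal axis), with a point per array and a line at the mean of the 2 arrays. Rb1 is lowest in the pRb-/-;p107-/- arrays, at -1.56 and -1.28, and both Rbl1 probe sets are lowest in the pRb+/+;p107-/- arrays.

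The arrays also differed by p107 status in probe sets that do not measure mouse genes, by tests chosen after the arrays were examined. The 24 poly-A control probe sets averaged 0.75 ± 0.59 (SD, n = 4 arrays) in the arrays of pRb+/+ and pRb-/-;p107+/+ skin and -0.75 ± 0.22 in the 4 p107-/- arrays, without overlap (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 arrays allow, and 0.1144 adjusted over 8 tests). The 18 hybridization controls averaged 0.62 ± 0.97 and -0.62 ± 0.21 in the same groups (exact permutation p = 0.0286, adjusted p = 0.1144), with pRb+/+ replicate 2 highest at 2.05. The poly-A controls also differed between genotypes of a p107 status, with 0.3 and 0.19 on the pRb+/+ arrays against 1.38 and 1.13 on the pRb-/-;p107+/+ arrays, and -0.57 and -0.55 on the pRb+/+;p107-/- arrays against -0.91 and -0.96 on the pRb-/-;p107-/- arrays. Split by pRb status, the exact permutation p was 0.6571 for the poly-A controls and 0.6857 for the hybridization controls (n = 4 arrays each). The other tests were on control probe sets for mouse beta-actin and Gapdh, 3 of each (exact permutation p from 0.1143 to 0.7714). After adjustment none of the 8 tests passed. Gapdh was nevertheless lowest on both pRb+/+ arrays, at -1.47 and -1.52 against -0.03 to 0.84 on the other 6. Beta-actin was 1.21 and 1.41 on the pRb-/-;p107+/+ arrays against -1 and -1.08 on the pRb-/-;p107-/- arrays. Comparisons with pRb+/+ skin therefore coincide with a difference in the Gapdh controls. Each comparison of p107-/- arrays with the others coincides with the difference in poly-A and hybridization controls, and cannot be made on either side of that. Both comparisons for pRb loss lie on 1 side of that difference, and within a p107 status if the pRb+/+ arrays keep p107. Pairs of arrays correlated across probe sets with a median r of 0.224 within a genotype, -0.024 between genotypes of the same p107 status and -0.284 between p107 statuses. Within a genotype r ran from 0.037 for the pRb-/-;p107+/+ arrays to 0.35. The former lay below the 0.076 of pRb+/+ replicate 1 with pRb-/-;p107+/+ replicate 2. Centring each probe set over 8 arrays alone would give unrelated arrays an r of about -0.143.

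**Figure D2:**
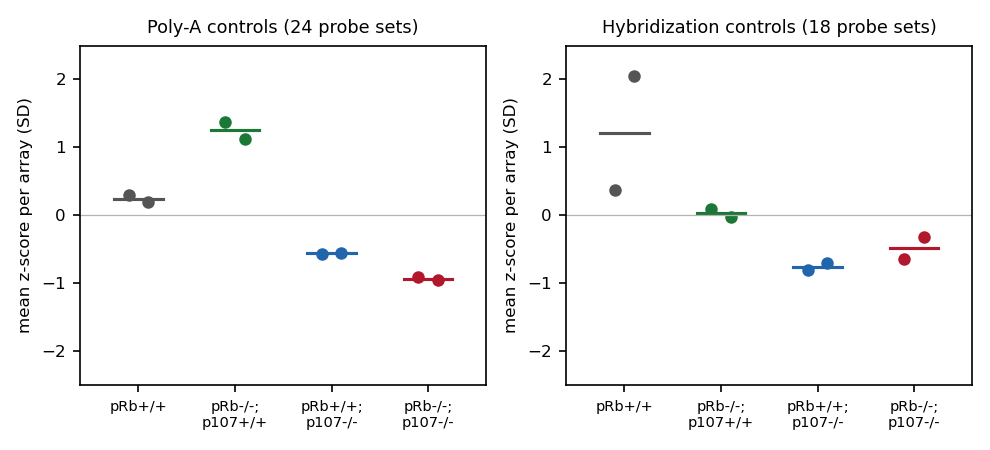
Mean z-score of the poly-A controls (left, 24 probe sets) and the hybridization controls (right, 18 probe sets) on each array (vertical axis, in SD) by genotype (horizontal axis), with a point per array and a line at the mean of the 2 arrays. For the poly-A controls the 4 p107-/- arrays lie between -0.96 and -0.55 and the other 4 between 0.19 and 1.38.

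The series compared the 4 genotypes, and its title concerns p107 in epidermis that lacks pRb. Among all 4 genotypes 289 probe sets differed (limma linear model without moderation, F test). The planned moderated test of limma called 0 probe sets in this and in every comparison below, where all counts come from the model without moderation. Leaving out an array gave 3 and 4 among genotypes without pRb+/+ replicate 1 and 2, 1 without either pRb+/+;p107-/- array and 0 without any other. Calls of single genes depended on the full set of arrays: of 148 calls of named genes, 24 held without either pRb-/-;p107+/+ array, 1 without either pRb+/+ array and 0 without any p107-/- array. By comparison, the number of changed probe sets ran from 0 for pRb loss where p107 was kept to 666 for loss of both proteins.

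**Figure D3:**
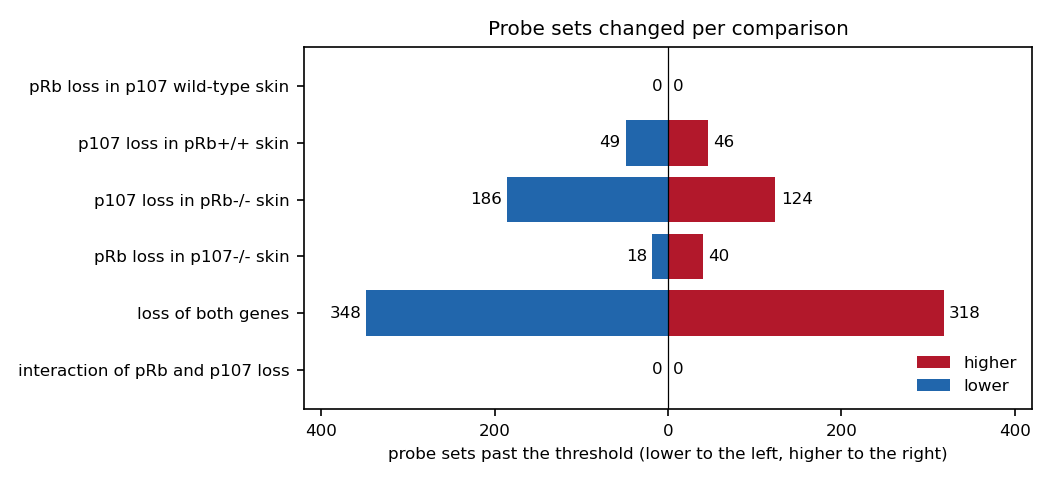
Number of probe sets past an adjusted p of 0.05 (horizontal axis) in each comparison (vertical axis), with bars to the right of 0 for higher and to the left for lower probe sets. Loss of both proteins has 318 higher and 348 lower probe sets, and pRb loss in p107 wild-type skin and the interaction have 0.

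With loss of pRb where p107 was kept, several gene lists passed but no single probe set did. Genes of S phase and DNA replication were higher as a set: 35 of 41 had a positive difference, with a median of 0.86, against a median of 0.1 over all genes (camera, adjusted p = 2.72e-05). Genes of G2 phase and mitosis were likewise higher (34 of 44 positive, median 0.95, adjusted p = 0.00264). Hair follicle genes were lower as a set, with 32 of 41 negative and a median of -0.63 (adjusted p = 2.67e-08). Adipocyte markers were higher (14 of 16 positive, median 1.12, adjusted p = 5.71e-06). The S phase call did not pass with fry (adjusted p = 0.0629), and the fry adjusted p of the hair follicle list was 0.0394. When adjusted over the list alone, 3 S phase genes and 1 G2 and mitosis gene were higher, 15 hair follicle genes were lower and 1 was higher, and 8 adipocyte genes were higher. Among members given as values, the DNA polymerase subunit gene Pole differed by 1.7 ± 0.42, the clamp loader gene Rfc3 by 1.82 ± 0.51, the centromeric histone gene Cenpa by 2.12 ± 0.6, the fatty acid transporter gene Cd36 by 2.4 ± 0.39 and the lipase gene Lipe by 2.11 ± 0.25. In the hair follicle list Hoxc13, which drives hair keratin genes, differed by -1.79 ± 0.73, while Shh, which encodes the Hedgehog ligand of the follicle bud, differed by 1.6 ± 0.29. The transcription factor gene E2f1 differed by 1.61 ± 0.48, with the opposite sign in its other probe set. None of these genes passed (limma, adjusted p from 0.13 for Lipe to 0.42 for Hoxc13).

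Of the other lists in this comparison, skeletal muscle markers were higher (23 of 29 positive, median 1.22, adjusted p = 0.00109), but the call was lost with an estimated correlation (adjusted p = 0.255) and without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.0958). Its members differed in sign, with 12 higher and 3 lower when adjusted over the list alone: the slow muscle gene Tnni1 differed by -2.62 ± 0.14 and the embryonic myosin gene Myh3 by -2.5 ± 0.35. Lipid and sterol synthesis genes were higher (16 of 21 positive, median 0.48, adjusted p = 0.0234), which was lost with an estimated correlation (adjusted p = 0.0988), after quantile normalization (adjusted p = 0.0551), with array medians subtracted (adjusted p = 0.116), without pRb+/+ replicate 1 (adjusted p = 0.185) and without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.1). The G2 and mitosis call was lost without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.0887). The largest positive differences of single genes were those of the cytokine receptor gene Il6st at 2.6 ± 0.23, Ascl2 at 2.59 ± 0.14 and Crk at 2.57 ± 0.29 (1 of its 4 other probe sets had the opposite sign). Among the most negative besides Tnni1 and Myh3 were Wnk1 at -2.5 ± 0.33 and the chemokine gene Cxcl12 at -2.5 ± 0.35. The limma linear model called 0 probe sets, with a smallest adjusted p of 0.0517 and 3026 probe sets at an unadjusted p below 0.05 against 1131 expected by chance. The moderated test also called 0. Leaving out an array gave 4 without pRb+/+ replicate 2, 1 without pRb+/+ replicate 1, 2 without pRb-/-;p107+/+ replicate 2 and 0 without any other.

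Loss of p107 in pRb+/+ skin went with a lower hair follicle list as a set (31 of 41 negative, median -1.62, against 0.4 over all genes, camera adjusted p = 1.58e-13), and 6 of its members fell while 35 did not pass. Counted when adjusted over the list alone, 24 fell and 3 rose. The hair keratin genes Krt86 (-2.12 ± 0.15, adjusted p = 0.0446) and Krt31 (-1.78 ± 0.07, adjusted p = 0.0313) fell, as did the keratin-associated protein gene Krtap16-3 (-1.77 ± 0.09) and Selenbp1 (-1.86 ± 0.06). Outside the list, the keratin-associated protein genes Krtap13-1 (-2.36 ± 0.09), Krtap15 (-2.32 ± 0.14) and Krtap19-2 (-2.16 ± 0.11) fell. Other genes with the largest falls were the adenylate kinase gene Ak3 (-2.55 ± 0.16), the galectin gene Lgals3 (-2.52 ± 0.12), Nfe2l3 (-2.51 ± 0.18), Psors1c2 (-2.5 ± 0.18) and Bambi (-2.38 ± 0.16), a pseudoreceptor of the TGF-beta family. Both other probe sets of Ak3 and 1 of the 2 others of Nfe2l3 had the opposite sign.

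Genes that rose with p107 loss in pRb+/+ skin included the sialyltransferase gene St3gal1 (2.55 ± 0.17), the tyrosine kinase gene Src (2.43 ± 0.14), Mcpt-ps1 (2.35 ± 0.1), Hoxc6 (2.35 ± 0.18), Ss18 (2.33 ± 0.14), Laptm4a (2.32 ± 0.15) and Cd74 (2.27 ± 0.14), the invariant chain of antigen presentation. The other probe set of Ss18 had the opposite sign. Mast cell markers were higher as a set (9 of 11 positive, median 1.53, adjusted p = 0.0161), although none of the 11 passed, and 4 rose and 1 fell when adjusted over the list alone. The mast cell receptor genes Kit and Fcer1a differed by 1.8 ± 0.72 and 1.98 ± 0.77. Schwann cell and nerve markers were lower (7 of 10 negative, median -1.04, adjusted p = 0.0215), with 3 lower when adjusted over the list alone, a call lost without pRb+/+ replicate 1 (adjusted p = 0.0991) and without pRb+/+;p107-/- replicate 2 (adjusted p = 0.101). With the replicate block the Schwann cell call was lost as well (camera adjusted p = 0.0748). The S phase list did not pass (28 of 41 positive, median 0.65, adjusted p = 0.205). Krt6b, a stress keratin gene, rose by 1.58 ± 0.1 and the cyclin gene Ccna2 fell by 1.95 ± 0.12, but the other probe set of Ccna2 had the opposite sign. Y-linked Eif2s3y differed by -2.44 ± 0.36 and Kdm5d by -2.28 ± 0.4, and Tsix, transcribed antisense to Xist, by 1.59 ± 0.45. None of these passed (adjusted p = 0.0905, 0.109 and 0.193), both other probe sets of Kdm5d had the opposite sign, and the sex of the pooled pups is not given in the labels.

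For p107 loss in pRb+/+ skin 95 probe sets passed (limma linear model, 46 higher and 49 lower), with the poly-A controls lower on the p107-/- arrays as described. The split was 25 higher and 51 lower after quantile normalization and 13 higher and 39 lower with array medians subtracted. The moderated test called 0, and leaving out an array gave 2 without pRb+/+ replicate 2, 1 without pRb+/+ replicate 1 and 0 without any other.

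Loss of p107 in pRb-/- skin went with differences in epidermal, hair and adipose genes. Stress keratinocyte genes were higher as a set (17 of 24 positive, median 1.49, against -0.05 over all genes, camera adjusted p = 4.58e-06), with 5 that rose, 19 that did not pass and 12 that rose and 1 that fell when adjusted over the list alone. They included the small proline-rich gene Sprr2d (1.66 ± 0.06, adjusted p = 0.0188), the interleukin 1 family genes Il1f9 (1.8 ± 0.1) and Il1f6 (2.16 ± 0.14), and Ereg (1.66 ± 0.11), which encodes a ligand of the EGF receptor. Spinous layer genes were higher (16 of 17 positive, median 1.37, adjusted p = 3.34e-05), among which Krtdap rose (2.05 ± 0.2), as did 4 when adjusted over the list alone. S phase genes were higher (34 of 41 positive, median 1.18, adjusted p = 4.71e-07), and the DNA primase gene Prim1 rose (1.18 ± 0.11, adjusted p = 0.0418), as did 6 S phase genes when adjusted over the list alone. The G2 and mitosis list went the other way without passing (29 of 44 negative, median -0.57, camera adjusted p = 0.0594), though fry called it lower (adjusted p = 0.0305). AP-1 and immediate early genes were higher (13 of 19 positive, median 0.51, adjusted p = 0.015), with Ier3 (2.03 ± 0.08) and Dusp1 (1.98 ± 0.18) past the threshold and 3 when adjusted over the list alone. That list's call was lost without pRb-/-;p107-/- replicate 1 (adjusted p = 0.0502).

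Hair follicle genes were lower (35 of 41 negative, median -1.43, adjusted p = 4.78e-09), and 6 fell, including Krt31 (-1.56 ± 0.07), Krt33a (-1.55 ± 0.12) and Krtap16-3 (-1.56 ± 0.09). Adjusted over the list alone, 23 fell and 3 rose. Adipocyte markers were lower (14 of 16 negative, median -2.23, adjusted p = 1.77e-07), with 3 that fell, and 12 that fell and 1 that rose when adjusted over the list alone: the adiponectin gene Adipoq (-2.54 ± 0.18, adjusted p = 0.0313), Cidea (-2.15 ± 0.13) and Pck1 (-2.54 ± 0.23), whose other probe set had the opposite sign. Fibroblast markers were lower (17 of 19 negative, median -1.17, adjusted p = 2.27e-04). The collagen gene Col5a1 fell (-1.86 ± 0.13), although both of its other probe sets had the opposite sign, and 6 members fell when adjusted over the list alone. Mast cell markers were higher (10 of 11 positive, median 1.69, adjusted p = 0.00131): the protease genes Tpsab1 (2.15 ± 0.13) and Cpa3 (1.91 ± 0.19) and the histidine decarboxylase gene Hdc (2.46 ± 0.14) rose, whereas the mast cell protease gene Mcpt4 fell (-2.36 ± 0.19), and 4 rose and 1 fell when adjusted over the list alone. Melanocyte markers were lower (8 of 9 negative, median -1.74, adjusted p = 0.00166), with Dct, an enzyme of melanin synthesis, falling (-2.01 ± 0.18) and 2 falling when adjusted over the list alone, but the call was lost without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.0579).

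Skeletal muscle markers were lower in this comparison (21 of 29 negative, median -1.24, adjusted p = 0.0137), with 1 that rose and 2 that fell, or 5 and 7 when adjusted over the list alone, a call lost with an estimated correlation (adjusted p = 0.242), without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.102) and without pRb-/-;p107-/- replicate 2 (adjusted p = 0.105). Sebocyte markers were lower (6 of 7 negative, median -1.13, adjusted p = 0.0414), with Cidea past the threshold and 2 that fell when adjusted over the list alone, which was lost after quantile normalization (adjusted p = 0.0507), without either pRb+/+ array (adjusted p = 0.0562 each), without pRb-/-;p107+/+ replicate 2 (adjusted p = 0.204) and without pRb-/-;p107-/- replicate 1 (adjusted p = 0.187). Further genes that rose were Grm8 (2.53 ± 0.26), Mink1 (2.51 ± 0.21), Spock2 (2.5 ± 0.26, with the opposite sign in its other probe set), Herpud1 (2.48 ± 0.24), a gene of the endoplasmic reticulum stress response, Bcl2l15 (2.46 ± 0.21), Psg18 (2.44 ± 0.16), S100a16 (2.43 ± 0.25) and Igfbp3 (2.42 ± 0.15). Kif1b rose by 2.5 ± 0.24, but 5 of its 6 other probe sets had the opposite sign. Further genes that fell were the muscle enzyme gene Pgam2 (-2.63 ± 0.16), Pon3 (-2.59 ± 0.25), Mgat1 (-2.58 ± 0.11), Nosip (-2.57 ± 0.22), Ets1 (-2.55 ± 0.14), Akr1c14 (-2.54 ± 0.25), the growth hormone receptor gene Ghr (-2.54 ± 0.24) and Tpm1 (-2.52 ± 0.25). In total 310 probe sets passed (limma linear model, 124 higher and 186 lower), again across the difference in poly-A controls, against 171 after quantile normalization (77 higher and 94 lower) and 137 with array medians subtracted (67 higher and 70 lower). The moderated test called 0. Leaving out an array gave 17 without either pRb+/+ array, of which 10 were among the 310, 0 without either pRb-/-;p107+/+ array and 1 without any other.

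Loss of pRb in p107-/- skin is the comparison made within the p107-/- arrays. S phase genes were higher as a set (37 of 41 positive, median 1.43, against -0.34 over all genes, camera adjusted p = 1.09e-16). Prim1 rose (1.88 ± 0.11, adjusted p = 0.0444), and 17 members rose when adjusted over the list alone. AP-1 and immediate early genes were higher (17 of 19 positive, median 1.64, adjusted p = 8.87e-11), with 1 that rose, Ier3 (2.08 ± 0.08), and 9 that rose when adjusted over the list alone. Stress keratinocyte genes were higher (16 of 24 positive, median 1.12, adjusted p = 1.28e-08): Sprr2d (2.02 ± 0.06), Sprr2h (2.23 ± 0.13) and Ereg (2.38 ± 0.11) were among the 4 that rose, while the stress keratin gene Krt6b fell (-2.52 ± 0.1), and 11 rose and 1 fell when adjusted over the list alone. Fibroblast markers were lower (18 of 19 negative, median -2.02, adjusted p = 6.16e-08). Col5a1 fell (-2.54 ± 0.13), with the same sign in both other probe sets, and 10 members fell when adjusted over the list alone. Adipocyte markers were lower (13 of 16 negative, median -1.09, adjusted p = 0.00338), with Adipoq at -1.81 ± 0.18 (adjusted p = 0.083) and 5 that fell when adjusted over the list alone.

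The p53 target genes were higher as a set (16 of 26 positive, median 0.39, adjusted p = 7.74e-04). None of them passed, Trp53inp1 differed by 2.6 ± 0.21 (adjusted p = 0.062) and Sesn1 by 2.47 ± 0.44 (adjusted p = 0.189), and 4 rose when adjusted over the list alone. Spinous layer genes were higher (10 of 17 positive, median 0.47, adjusted p = 0.00137), with Ovol1, a transcription factor of differentiating epidermis, rising (2.37 ± 0.15) and with 5 that rose and 1 that fell when adjusted over the list alone. Hair follicle genes were lower (34 of 41 negative, median -0.56, adjusted p = 5.66e-04), 5 of them when adjusted over the list alone, but this call depended on scaling: it was lost after quantile normalization (adjusted p = 0.61) and with array medians subtracted (adjusted p = 0.0733). Granular layer and cornified envelope genes were higher (16 of 28 positive, median 0.91, adjusted p = 0.0287), a call lost after quantile normalization (adjusted p = 0.0503), with array medians subtracted (adjusted p = 0.0628), without either pRb+/+;p107-/- array (adjusted p = 0.055 and 0.0546) and without pRb-/-;p107-/- replicate 1 (adjusted p = 0.176). Its mean difference was 0.25, 12 of the 28 were negative, its member Lce1i fell (-2.2 ± 0.14), and 10 rose and 4 fell when adjusted over the list alone. The G2 and mitosis list was higher (25 of 44 positive, median 0.21, adjusted p = 0.035), with 0 members past the threshold even when adjusted over the list alone, which was lost without either pRb-/-;p107+/+ array (adjusted p = 0.0541 each), without pRb+/+;p107-/- replicate 1 (adjusted p = 0.225) and without pRb-/-;p107-/- replicate 1 (adjusted p = 0.229). The E2f8 difference of 2.38 ± 0.44 did not pass (adjusted p = 0.194).

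The genes with the largest rise for pRb loss in p107-/- skin were Slurp1 (2.62 ± 0.12), a secreted epidermal protein gene, Errfi1 (2.61 ± 0.06), a feedback inhibitor of the EGF receptor, Pdk4 (2.6 ± 0.17), Sult2b1 (2.58 ± 0.15), a cholesterol sulfotransferase gene, and Tsc22d3 (2.46 ± 0.1), a glucocorticoid-induced gene. Besides Col5a1, Krt6b and Lce1i, the largest falls were those of Rpl37a (-2.29 ± 0.14) and Timm22 (-2.21 ± 0.11). In total 58 probe sets passed (limma linear model, 40 higher and 18 lower). The split was 65 higher and 12 lower after quantile normalization and 2 higher and 0 lower with array medians subtracted. The moderated test called 0, and leaving out an array gave 2 without either pRb-/-;p107+/+ array, 0 without either pRb-/-;p107-/- array and 1 without any other.

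Loss of both proteins against pRb+/+ skin gave the most changed probe sets. S phase genes were higher almost throughout: 40 of 41 were positive, with a median of 1.94 against 0.14 over all genes (camera adjusted p = 1.79e-11), 6 rose, 35 did not pass, and 20 rose when adjusted over the list alone. They included the replicative helicase gene Mcm5 (2.6 ± 0.2, adjusted p = 0.0236), the ribonucleotide reductase gene Rrm2 (2.55 ± 0.26), Prim1 (2.51 ± 0.11) and the replication licensing gene Cdc6 (2.48 ± 0.25). The G2 and mitosis list did not pass (28 of 44 positive, median 0.56, adjusted p = 0.563). Hair follicle genes were lower (32 of 41 negative, median -2.04, adjusted p = 2.16e-12), 20 of the 41 fell and 24 fell and 2 rose when adjusted over the list alone. The examples were Krt31 (-2.5 ± 0.07, adjusted p = 0.00889), Krt33a (-2.49 ± 0.12), Krtap16-3 (-2.5 ± 0.09) and Selenbp1 (-2.42 ± 0.06).

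Stress keratinocyte genes were higher with loss of both proteins (19 of 24 positive, median 1.13, adjusted p = 4.06e-05), with 7 that rose and 1 that fell, and with 13 and 2 when adjusted over the list alone. Sprr2d rose by 2.48 ± 0.06, Il1f9 by 2.56 ± 0.1, Ereg by 2.16 ± 0.11 and Sprr2h by 2.29 ± 0.13. Spinous layer genes were higher (14 of 17 positive, median 1.64, adjusted p = 2.03e-04), with the desmosomal cadherin gene Dsc1 (2.62 ± 0.17), Krtdap (2.4 ± 0.2) and Ovol1 (2.15 ± 0.15) rising, and 6 when adjusted over the list alone. AP-1 and immediate early genes were higher (14 of 19 positive, median 1.46, adjusted p = 0.0036), with Ier3 (2.31 ± 0.08) and Dusp1 (2.19 ± 0.18) past the threshold and 6 when adjusted over the list alone. The p53 targets were higher (22 of 26 positive, median 1.3, adjusted p = 0.0106), with no member past the threshold and 4 that rose when adjusted over the list alone. Mast cell markers were higher (10 of 11 positive, median 1.65, adjusted p = 0.00166): Tpsab1 (2.24 ± 0.13), Hdc (2.01 ± 0.14) and Cpa3 (1.79 ± 0.19) rose and Mcpt4 fell (-2.16 ± 0.19), against 4 and 1 when adjusted over the list alone.

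Markers of several other cell types were lower with loss of both proteins. Adipocyte markers were lower (12 of 16 negative, median -1.17, adjusted p = 0.004), with Cidea falling (-1.83 ± 0.13), and 2 that rose and 7 that fell when adjusted over the list alone. Fibroblast markers were lower (17 of 19 negative, median -1.04, adjusted p = 6.05e-04), with the extracellular matrix genes Dpt (-2.25 ± 0.29) and Fn1 (-2.22 ± 0.28) among 3 that fell and 4 that fell when adjusted over the list alone, but with an estimated correlation the adjusted p was 0.0547. Col5a1 fell by 1.43 ± 0.13, but both of its other probe sets had the opposite sign. Melanocyte markers were lower (7 of 9 negative, median -1.66, adjusted p = 0.0093), with Dct falling (-2.46 ± 0.18), and 3 when adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.0848), without pRb+/+ replicate 1 (adjusted p = 0.0548) and without pRb-/-;p107-/- replicate 1 (adjusted p = 0.0947). Schwann cell markers were lower (7 of 10 negative, median -1.8, adjusted p = 0.0444), with the myelin gene Pmp22 (-2.47 ± 0.3) among 2 that fell and 3 that fell when adjusted over the list alone, and this was lost without either pRb+/+ array (adjusted p = 0.178 and 0.0786), without pRb-/-;p107-/- replicate 1 (adjusted p = 0.0956) and after quantile normalization (adjusted p = 0.0526). With the replicate block the Schwann cell call was lost too (camera adjusted p = 0.101). The largest single-gene rises besides Dsc1 and Mcm5 were Aqp3 (2.59 ± 0.24), the epidermal glycerol channel, Cd109 (2.59 ± 0.26) and Tnfrsf23 (2.59 ± 0.12). The largest falls were Sec22b (-2.61 ± 0.2), Ltbp3 (-2.61 ± 0.17), Kifap3 (-2.6 ± 0.22), Aox4 (-2.6 ± 0.18) and Krtap3-1 (-2.59 ± 0.21). Xist differed by -1.76 ± 0.26 (adjusted p = 0.0611). In total 666 probe sets passed (limma linear model, 318 higher and 348 lower), across the same difference in poly-A controls, and the moderated test called 0. Leaving out an array gave 242 without either pRb-/-;p107+/+ array, 169 of them among the 666, but 3 and 2 without pRb+/+ replicate 1 and 2, 1 without either pRb+/+;p107-/- array and 0 without either pRb-/-;p107-/- array.

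**Figure D4:**
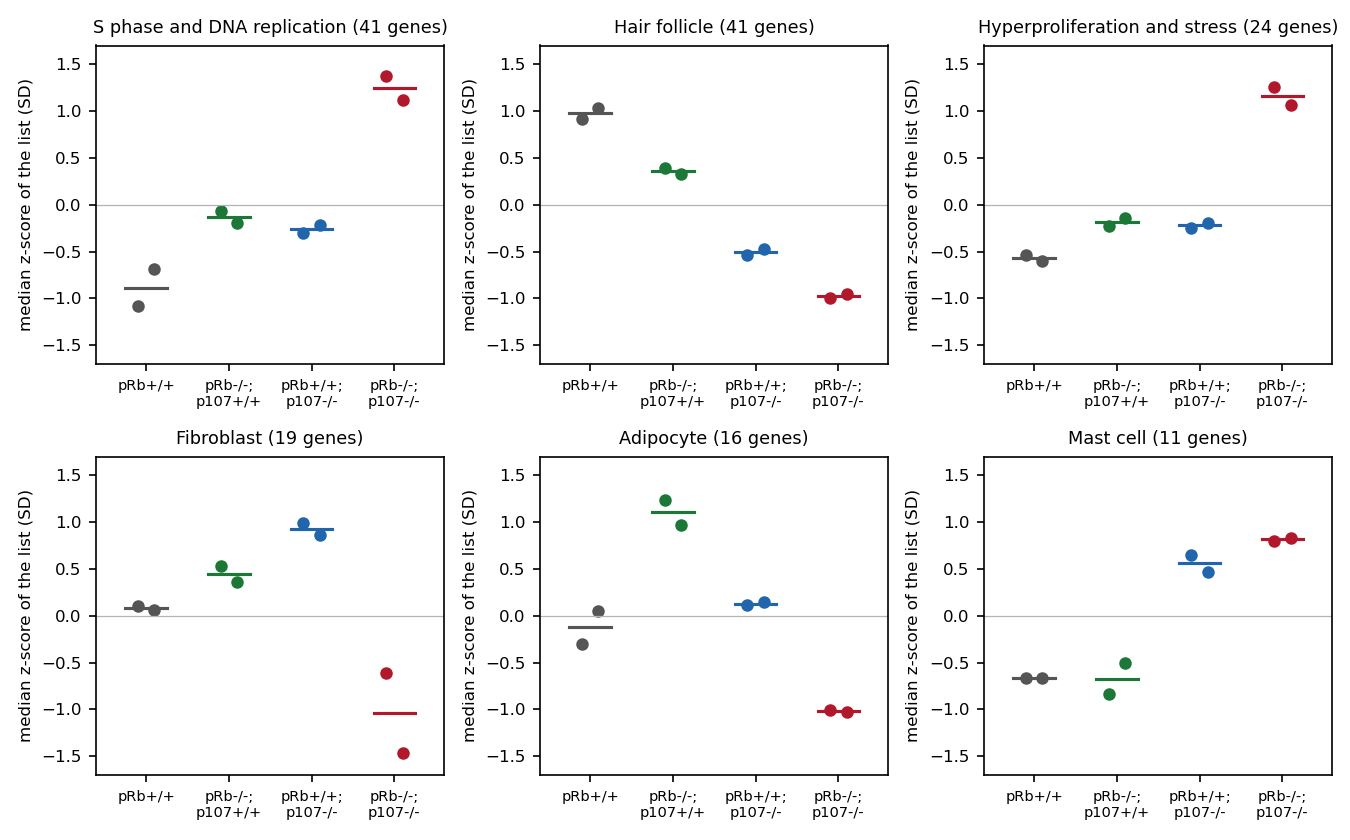
Median z-score of the genes of 6 lists on each array (vertical axis, in SD) by genotype (horizontal axis), with a point per array and a line at the mean of the 2 arrays. S phase medians are 1.37 and 1.12 in the pRb-/-;p107-/- arrays and -0.69 or lower in the pRb+/+ arrays, hair follicle medians run from 1.03 in pRb+/+ replicate 2 to -0.99 in pRb-/-;p107-/- replicate 1, and mast cell medians are above 0 in the 4 p107-/- arrays.

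Whether pRb loss acted differently with and without p107 was tested as an interaction, which is positive where the difference for pRb loss is higher in p107-/- skin. Over all genes its median was -0.44. Whether the scores were made from log or linear values is not known, and an interaction on 1 scale need not hold on the other. Stress keratinocyte genes had a positive interaction (19 of 24 positive, median 1.19, camera adjusted p = 5.83e-06), as did AP-1 and immediate early genes (13 of 19, median 1.81, adjusted p = 3.79e-05) and S phase genes (29 of 41, median 0.49, adjusted p = 3.82e-04). Adipocyte markers had a negative interaction (14 of 16 negative, median -2.23, adjusted p = 5.83e-06) and so did fibroblast markers (17 of 19 negative, median -2.08, adjusted p = 3.79e-05). When adjusted over the list alone, 10 stress genes and 5 AP-1 genes were higher, 1 stress gene was lower, and 10 adipocyte and 4 fibroblast genes were lower. As values, Egr1 had an interaction of 2.77 ± 0.26, the EGF receptor ligand gene Tgfa 3.06 ± 0.57, Lipe -3.58 ± 0.35, the collagen gene Col1a1 -3.26 ± 0.69 and the CDK inhibitor gene Cdkn1a 2.85 ± 0.49. Both other probe sets of Tgfa and the other probe set of Col1a1 had the opposite sign. These 5 of the 9 lists that passed held without any single array, although the S phase call did not pass with fry (adjusted p = 0.209). Camera ranks a list against all other genes, so a positive call can arise where the other genes are more negative. Over all genes, the most positive were Atpif1 (3.6 ± 0.25), Tshz1 (3.52 ± 0.57) and Irx3 (3.49 ± 0.49), and the most negative Acpp (-3.67 ± 0.26), Gosr2 (-3.63 ± 0.33) and Rps18 (-3.62 ± 0.42), where the other probe set of Atpif1 and 3 of the 5 others of Rps18 had the opposite sign. The limma linear model called 0 probe sets (smallest adjusted p = 0.0502, 2964 at an unadjusted p below 0.05 against 1131 expected), and the moderated test called 0. Leaving out pRb+/+ replicate 1, pRb-/-;p107-/- replicate 1 or either pRb+/+;p107-/- array gave 1 each, and leaving out any other gave 0.

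Across 12393 genes, the differences for pRb loss with and without p107, which share no array, correlated with Pearson's r = -0.001 and Spearman's rho = -0.001, and 48.8% had the same sign. For p107 loss with and without pRb, r was 0.263 and rho 0.267, 60.1% had the same sign, and 18 genes fell in both against 0.244 expected of independent lists, with 3 that rose in both against 0.101. Both differences for p107 loss cross the difference in control probe sets. The calls for p107 loss in both backgrounds also share each probe set's residual spread. Their overlap can therefore exceed the expected numbers without a shared effect. Genes are not independent replicates, so these values describe the arrays. An r near 0 can also arise from noise, and the 2 pRb-/-;p107+/+ arrays correlated with an r of only 0.037.

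Of the 29 lists, 13 passed in none of the 6 comparisons by camera with the preset correlation. Their smallest adjusted p was 0.0507 for inflammatory cytokines and chemokines, 0.0756 for smooth muscle markers, 0.0777 for the Rb family and E2F factors, 0.078 for sex-linked genes, 0.132 for interferon response genes, 0.166 for Wnt, Hedgehog and Notch response genes, 0.26 for macrophage and myeloid markers and 0.354 for erythroid markers. It was 0.373 for apoptosis genes, 0.437 for lymphocyte markers, 0.46 for CDK inhibitors and G1 cyclins, 0.464 for endothelial markers and 0.498 for basal keratinocyte genes. An estimated correlation or fry called 4 of these 13, and lists gained under the remaining settings are not listed here. With an estimated correlation, inflammatory cytokines and chemokines passed as higher for p107 loss in pRb-/- skin (adjusted p = 0.0391), pRb loss in p107-/- skin (0.038) and loss of both proteins (0.0434, and 0.0239 with fry). With fry alone, sex-linked genes passed as lower for p107 loss in pRb+/+ skin (adjusted p = 0.00965), p107 loss in pRb-/- skin (0.0375) and loss of both proteins (0.00778). That list mixes Xist and Tsix with Y-linked genes, so its single direction cannot be read as a difference in sex. For p107 loss in pRb+/+ skin 2 of its 5 genes were positive and 3 negative, and 1 rose and 3 fell when adjusted over the list alone. A difference in the sex of the pooled pups therefore stays open in this comparison. Fry also called Wnt, Hedgehog and Notch response genes lower for pRb loss in p107-/- skin (0.0228) and macrophage and myeloid markers higher for p107 loss in pRb+/+ skin (0.0499).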

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

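The tests of explanations in this part were chosen after the results were seen, while the lists and the interaction contrast were fixed before the data were examined. The unmoderated statistic and the choice of probe sets for the list test were changed once the values were found to be scores. For 9 lists the interaction of pRb and p107 loss ranked apart from that of all other genes, whose median was -0.44, by camera. That holds for the scale behind the scores, log or linear, which is not known. The adjusted p was 5.83e-06 for stress keratinocyte genes, 5.83e-06 for adipocyte markers, 3.79e-05 for AP-1 and immediate early genes, 3.79e-05 for fibroblast markers and 3.82e-04 for S phase genes. These 5 calls held without any single array and with an estimated correlation. With fry, which tests a list by itself, 4 of the 9 passed, while S phase did not (adjusted p = 0.209). The other 4 calls were weaker: hair follicle (0.0246, with a median of 0.21 and a mean of 0), skeletal muscle (0.0246), spinous layer (0.04) and p53 targets (0.0463), none of which passed with fry (0.869, 0.109, 0.193 and 0.198). The hair follicle call was also lost with gene averages (0.13), so no difference in the effect on this list is claimed. The hair follicle call was lost without pRb+/+ replicate 2 (0.0888), pRb-/-;p107+/+ replicate 2 (0.0708) and pRb+/+;p107-/- replicate 1 (0.0679). The skeletal muscle call was lost without replicate 2 of pRb-/-;p107+/+ (0.158), of pRb+/+;p107-/- (0.0549) and of pRb-/-;p107-/- (0.133). The spinous layer call was lost without pRb+/+ replicates 1 and 2 (0.0627 and 0.21), pRb-/-;p107+/+ replicates 1 and 2 (0.0504 and 0.113) and pRb+/+;p107-/- replicates 1 and 2 (0.0679 and 0.0572). The p53 target call was lost without pRb+/+ replicates 1 and 2 (0.143 and 0.0888), pRb-/-;p107+/+ replicates 1 and 2 (0.167 and 0.0686), pRb+/+;p107-/- replicate 2 (0.116) and pRb-/-;p107-/- replicate 1 (0.061). With an estimated correlation, the adjusted p was 0.359 for skeletal muscle and 0.0696 for spinous layer.

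Stress keratinocyte genes were higher and fibroblast genes lower in pRb-/-;p107-/- skin than in the other genotypes, but against pRb+/+ skin the fibroblast call was lost with an estimated correlation (adjusted p = 0.0547). A processing difference along p107 status is argued against for the stress genes, because they were higher for pRb loss among the p107-/- arrays alone (adjusted p = 1.28e-08). A larger share of epidermis in these pieces of skin would lower the markers of all dermal cell types alike, though scores do not show by how much. It would also raise epidermal genes. The basal keratinocyte list passed in no comparison (smallest camera adjusted p = 0.498), but its medians of -0.96 and 0.31 on the pRb+/+ arrays leave this undecided. Spinous layer genes were higher for loss of both proteins (median difference 1.64), while adipocyte markers were lower (-1.17). Within the p107-/- arrays, the mast minus fibroblast list median differed by 2.22 ± 0.36 for pRb loss (SE of a linear model). Against pRb+/+ skin, mast cell markers also follow the difference in control probe sets, being higher in all p107-/- arrays. With these limits, mast cell markers do not decide on a larger epidermal share as the whole cause. Their list median per array parted from that of fibroblasts by 2.59 ± 0.36 for loss of both proteins (SE of a linear model, 2 arrays per genotype). With any array left out this ran from 2.15 to 3.04. These differences take in the fibroblast fall that is to be explained. Mast medians themselves were 0.8 and 0.83 on the pRb-/-;p107-/- arrays against 0.65 and 0.47 on the pRb+/+;p107-/- arrays. A larger epidermal share alone would lower them, but a change in mast cells could offset that, so both stay open. Endothelial minus fibroblast medians parted the same way but less clearly, by 1.51 ± 0.51 (0.88 ± 0.35 without pRb+/+ replicate 1). For pRb loss in p107-/- skin they parted by 1.8 ± 0.51 (1.49 to 2.11 with any array left out), and they take in the same fall. Handling of the skin before extraction may raise immediate early genes, whose list medians were 0.7 and 0.89 in the pRb-/-;p107-/- arrays against at most 0.25 in the other 6, and it cannot be told apart from genotype, which stays open like any processing difference that follows each genotype.

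Hair follicle genes were lower in each mutant genotype than in pRb+/+ skin. A processing difference along p107 status is argued against as the whole cause. Among the arrays not labelled p107-/-, the list was also lower for pRb loss (camera adjusted p = 2.67e-08, fry adjusted p = 0.0394). More deep tissue in the excised skin is argued against where pRb-/-;p107-/- skin was compared, since adipocyte markers were lower there too (median -1.17 against pRb+/+ skin), although for pRb loss in p107-/- skin the hair call itself was lost after quantile normalization (adjusted p = 0.61) and with array medians subtracted (0.0733). In the single mutants more deep tissue cannot be told apart. For pRb loss where p107 was kept adipocyte markers were higher while fibroblast markers, with a median of -0.12, did not pass. Less deep tissue in pRb-/-;p107-/- skin, where adipocyte and fibroblast markers were lower, was not tested and stays open. So do genotype, age in hours and a processing difference that sets the pRb+/+ arrays apart, as the Gapdh controls do.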

How the results depend on the processing

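None of the 50 list calls and 148 calls of named genes reversed its direction under the alternatives run. For named genes, however, the moderated test and the replicate block keep each difference, so they could not reverse a call. Nor could a left-out array where the arrays compared did not overlap. The counts of called probe sets depended on the setting. The cause was not tested, except where fewer residual degrees of freedom or fewer tested features follow from the alternative itself. The counts of 95, 310, 58 and 666 probe sets (p107 loss in pRb+/+ skin, p107 loss in pRb-/- skin, pRb loss in p107-/- skin and loss of both) and of 289 among the 4 genotypes all became 0 with the moderated test that the design had named, robust or not. Fits of only the genotypes compared, with fewer degrees of freedom, gave 0, 0, 0 and 1. With the replicate block they were 1, 2, 0 and 37, with 3 among the 4 genotypes and 1 for pRb loss where p107 was kept. Array medians subtracted gave 52, 137 and 2 for the first 3 and 97 among genotypes, quantile normalization 171 for p107 loss in pRb-/- skin, 370 for loss of both and 150 among genotypes, and array weights 163 and 209 for p107 loss in pRb-/- skin and pRb loss in p107-/- skin. With probe sets averaged per gene, and so fewer features tested, the counts were 41, 203 and 400 for p107 loss in pRb+/+ skin, p107 loss in pRb-/- skin and loss of both, 3 for pRb loss where p107 was kept, 24 for the interaction and 178 among genotypes. Of the probe sets called in the main setting, 33, 114, 31 and 315 were also called after quantile normalization.

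Leaving out each array in turn, with 3 residual degrees of freedom and the lone array assumed to vary like the others, gave 0 to 4 probe sets for pRb loss where p107 was kept, 0 to 2 for p107 loss in pRb+/+ skin, 0 to 17 for p107 loss in pRb-/- skin, 0 to 2 for pRb loss in p107-/- skin, 0 to 242 for loss of both, 0 to 1 for the interaction and 0 to 4 among genotypes. Lists past the threshold numbered 3 to 6, 2 to 4, 8 to 12, 8 to 11, 10 to 12 and 5 to 9 in the same order of comparisons, against 6, 3, 11, 10, 11 and 9. Lists for p107 loss in pRb+/+ skin numbered 6 with gene averages and 7 with fry, and for the interaction 5 with the replicate block and 4 with fry. Of 50 list calls, 46 held with array medians subtracted (chosen after seeing the data for lists), 44 with quantile normalization, 44 with the replicate block, 49 with gene averages, 38 with fry and 39 without pRb-/-;p107+/+ replicate 2, the array whose absence cost the most. Of 148 calls of named genes, 84 held after quantile normalization, 78 with array medians subtracted and 11 with the replicate block, 0 with the robust moderated test and 0 to 24 with 1 array left out. Replicate numbers 1 and 2 recur in every genotype, but differences between the numbers correlated between genotypes with r from -0.131 to 0.105, so the samples share only a number. The correlation of pRb loss effects lay between -0.006 and 0.027 (main setting -0.001) and that of p107 loss effects between 0.265 and 0.288 (main setting 0.263) over quantile normalization, gene averages and all probe sets, the last chosen after seeing the data. The filter on dim probe sets, the minimum of 2-fold and the mean-variance trend were not run, because scores hold no levels. Limits from signal over background are unknown for the same reason.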

Other observations

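The tests in this part were chosen after the data were seen. Genes were grouped by the letters that open their symbol, which gave 153 families of 10 or more genes, tested with camera and adjusted over the families of a comparison. The 26 keratin-associated protein genes (Krtap), which encode hair shaft proteins, were lower in each of the 5 comparisons of genotypes, with medians of -1 for pRb loss where p107 was kept (adjusted p = 1.48e-21), -1.73 and -1.41 for p107 loss in pRb+/+ and pRb-/- skin, -0.73 for pRb loss in p107-/- skin (adjusted p = 2.24e-06) and -2.43 for loss of both (adjusted p = 2e-22, where 20 of the 26 fell). For the interaction they ranked higher (18 of 26 positive, median 0.26, adjusted p = 0.00243) among genes whose median was -0.44, and the call held after quantile normalization (median 0.57, adjusted p = 4e-05) and with array medians subtracted (median 0.72, adjusted p = 2.6e-07). No member passed in that test. For p107 loss in pRb-/- skin 14 of 15 genes with the symbol Klk were positive (median 1.13, adjusted p = 0.0195) though none passed, as were 11 of 14 Serpinb genes (median 1.25, adjusted p = 0.0272), of which 1 rose. For pRb loss in p107-/- skin both groups ranked higher with fewer positive members, 10 of 15 Klk genes (adjusted p = 0.0263) and 8 of 14 Serpinb genes (adjusted p = 0.00705). The late cornified envelope genes (Lce) were lower for loss of both (median -2.02, adjusted p = 0.00627), although 1 of the 11 rose and 3 fell. They were also lower for pRb loss where p107 was kept (median -0.97, adjusted p = 0.0223) and for pRb loss in p107-/- skin (median -1.84, adjusted p = 0.00705), with 2 of 11 positive in each. All 11 belong to the granular layer and cornified envelope list of 28 genes, so that list was split for pRb loss in p107-/- skin, where it ranked higher as a whole. With loss of both, Lce3c rose by 2.42 ± 0.22 and Lce1i fell by 2.33 ± 0.14. After quantile normalization the Krtap call for pRb loss in p107-/- skin was lost (median -0.37, adjusted p = 0.491) and it weakened with array medians subtracted (median -0.45, adjusted p = 0.0391). The Serpinb call for p107 loss in pRb-/- skin was also lost after quantile normalization (adjusted p = 0.0505), and the other Krtap, Klk, Serpinb and Lce calls held under both.

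Genes of mitochondrial complex I were lower for loss of both (Ndufa median -1.94 and Ndufb median -1.87, adjusted p = 0.0152 each), but with an estimated correlation the adjusted p was 0.595 for each. For pRb loss in p107-/- skin, 13 of 18 Dusp genes and 10 of 14 Klf genes were positive, with adjusted p of 0.0228 and 0.00705, and with an estimated correlation 0.06 and 0.00391.

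Arrays of different p107 status correlated with a median r of -0.284, against -0.024 for different genotypes of the same p107 status and about -0.143 for unrelated arrays after centring. A processing batch that follows p107 status is a candidate explanation: the poly-A controls, which are not mouse transcripts, differed by -1.5 SD between the p107-/- arrays and the others. It cannot be told apart from p107 loss, because every p107-/- array lies on the same side of that difference.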
